A study of Mus musculus with 3 samples.

How the data were processed

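Primary tumour cells of 4 C3(1)-Tag mice were cultured in collagen I or Matrigel in medium with 2.5 nM FGF2, and 4T1 cells on plastic, per the labels' protocols. Cells were released from the gels (collagenase for collagen, EDTA on ice for Matrigel), dissociated, barcoded by condition with MULTI-seq, pooled, sorted as live cells with propidium iodide and run on the 10x Genomics 3' v2 chemistry, per the labels' protocols. The submitters' processing notes name Cell Ranger 3.0.2, Scanpy 1.4.4 and the GRCm38/mm10 build, without roles; the annotation release is not given in the sources used here. The deposited matrix holds raw UMI counts per gene and cell, and all of its 39668312 entries were whole numbers. The deposited cell annotation gives the day, mouse and matrix of each cell, its total UMI count and the mitochondrial fraction of its counts, which matched the matrix; the highest mitochondrial share was 9.99% and the fewest genes per cell 270, which may reflect filters before deposit. Its first time point, D1, was taken as the day 0 pool because the other 2 match by name, and its batch column, which joins D1 and D3, was not used. The mouse and matrix of a cell came only from that annotation, and 0 columns of per-sample values were left unused. Of 20605 gene identifiers, 20574 were matched to GENCODE vM21, the source of the coordinates given.

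The main design, the gene lists, the marker lists, the rule for named genes and most alternative settings were fixed before the data were examined. Cells were scaled to 10000 counts, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 gave 24 clusters (Scanpy 1.11.5, leidenalg 0.10.2, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Python 3.11.15; figures with matplotlib 3.10.9). Clusters were named from the fixed markers, with 20 CPM as pseudocount for ranking, and cells in macrophage-like, fibroblast-like and T and NK-like clusters were left out. No doublet caller was run. On simulated data of 1550 cells of 4 types over 20605 genes, 9 clusters were found and 99.8% of cells lay in a cluster led by their type.

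UMI counts were summed per mouse, matrix and day over at least 20 cells, which gave 21 sums. Genes passing edgeR's expression filter (13184) were tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling and a quasi-likelihood F test in 1 fit with 6 groups (common dispersion 0.0853, prior degrees of freedom 3.93). The p-values were adjusted by Benjamini-Hochberg within each of 9 comparisons, and genes with an adjusted p under 0.05 were called. CPM are counts relative to the scaled total of their sum, fold changes are log2 values and positive for collagen over Matrigel or for the later day. The change of the matrix difference is the later difference minus that of day 0. The replicate is the mouse. The same 4 animals were used in both matrices and on all days per the labels, so the mouse number pairs the sums, and a fit with the mouse as a block was set in advance as the other design (common dispersion 0.0256). Deviations from group means correlated between sums of the same mouse with a median of 0.468 (lowest 0.085, highest 0.816; other mice -0.132), and 21 of 21 sums correlated best with their own mouse. Counts of the 28 pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 8.0 to 70.4), so no sum was a copy of another.

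The 30 gene lists and 10 cell type marker lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated correlation, adjusted over the lists of a comparison, and the calls that hold with an estimated correlation are given beside each list. Per comparison the named genes were the 10 highest and 10 lowest log2 fold changes among called genes of at least 20 CPM with the same sign in every mouse, without predicted, mitochondrial and ribosomal protein genes; up to 4 members with the smallest p of each list with a set test under 0.05 or at least 3 members passing; and 12 state markers (Vim, Krt14, Krt5, Krt8, Cdh1, Epcam, Fn1, Trp63, Snai2, Zeb1, Twist1 and Mki67). The text gives a selection of these genes; 144 genes were followed through the alternatives, and some genes are not reported here. Genes with near-identical copies (Hspa1a and Hspa1b, histone cluster genes, Ifitm2 and Ifitm3) or overlapping neighbours may have had their reads split or dropped in counting and are uncertain. For the 4T1 line, which had 1 sum per pool, log2 changes used CPM with a pseudocount of 5 and have no error.

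Shares of cells with a Vim or Krt14 UMI were computed after thinning each cell to 2000 UMIs. Shallower cells were left out, 84 of 939, 11 of 2477 and 1 of 1064 in collagen and 138 of 1701, 19 of 687 and 2 of 102 in Matrigel on days 0, 3 and 5. Mouse shares were compared with an exact two-sided permutation test. Intervals of shares are exact (Clopper-Pearson) 95% intervals and cover counting error only. On counts simulated with 100 genes changed 2-fold and 100 changed 4-fold, edgeR found 75% and 97% of them at day 0 (12898 genes tested), 72% and 99% on day 3 (12938) and 48% and 95% on day 5 (12882). The figures were 82% and 99% for day 3 against day 0 in collagen (12895 genes), 71% and 95% for day 5 against day 3 (12922), 78% and 98% (12903) and 45% and 93% (12922) for the same steps in Matrigel, and 45% and 93% (12918) and 22% and 88% (12925) for the changes of the matrix difference by day 3 and day 5. Unchanged genes made up 1.72 to 7.38% of the calls of edgeR. On days 0 and 5 they made up 11.6 and 16.3% of those of DESeq2 and 5.56 and 10.7% of those of limma. In each comparison camera called 0 of 30 unchanged lists. The simulated counts were drawn for each gene on its own, without correlation between genes and without an effect of the mouse. These rates therefore do not carry over to correlated lists or to sums paired by mouse.

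The other settings fixed in advance were DESeq2's size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, the mouse block, all cells, at least 100 cells per sum, limma on log2 values averaged over cells, a fit of only the groups compared, each mouse left out in turn, subtraction of the change in 4T1, and for shares other thinning depths and calls of 2 or more UMIs. Chosen after seeing the data were fits without the 57 mouse-labelled cells of the 4T1 cluster (with and without the block), without the cluster of few UMIs, and with at least 10 cells per sum.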

Results

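Single-cell transcriptomes were collected from primary mammary tumour cells of 4 C3(1)-Tag mice, a transgenic line in which a viral large T antigen drives mammary carcinoma. The cells of each mouse were cultured in collagen I, the main fibrous collagen of stroma, or in Matrigel, a laminin-rich basement membrane extract. There were 3 samples, each a pool of both matrices and all mice present on 1 day (day 0, taken 12 h after plating, day 3 and day 5). The cell annotation calls its first time point D1, and its match to day 0 is an inference. MULTI-seq, a lipid-anchored barcode, marked the mouse and the matrix of each cell. Cells of 4T1, an established metastatic mouse mammary carcinoma line, were part of every pool. The comparisons ask how cells of the same tumours differed between the matrices on each day, whether that difference changed with time, and how each culture changed over time. Cells were released from collagen with collagenase and from Matrigel with EDTA on ice, so the matrix comparison includes this difference in handling. Each day was 1 pool and 1 batch in the labels, so day and batch cannot be told apart within a matrix, whereas both matrices of a day shared their pool.

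The count matrix held 7620 cells, 20605 genes, with a median of 31767 UMIs per cell. The samples of days 0, 3 and 5 held 60391888, 140869562 and 68725854 UMIs in total. Collagen cultures gave 1018, 2556 and 1075 cells on days 0, 3 and 5, with medians of 15052, 36162 and 54762 UMIs per cell. Matrigel cultures gave 1845, 711 and 102 cells, with medians of 15865, 40679 and 59399 UMIs, and the 4T1 line 98, 196 and 19 cells. Clustering named 227 macrophage-like, 81 fibroblast-like and 29 T and NK-like cells among the 7307 tumour cells, and these 337 cells were left out. The remaining 6970 cells made 21 sums of 1 mouse, matrix and day, with 38 to 1148 cells and 1831436 to 46657709 UMIs each. Mouse 4 had no cells on day 5, and the 13 Matrigel cells of mouse 1 on that day were below the minimum of 20, so day 5 set 3 collagen sums against 2 Matrigel sums. A cluster of few UMIs (median 2670), with Hspa1a, Hspa1b and Cx3cr1 among its 10 leading genes, held 571 tumour cells, 307 of them of mouse 4 on day 0. Another 2 unnamed clusters held 604 cells, and all 3 stayed in the sums. The 2 unnamed clusters made up 7.96%, 9.90% and 22.05% of all collagen cells on days 0, 3 and 5. In Matrigel they made up 0.70%, 2.25% and 3.92%. Their epithelial markers were low, with mean log2 ratios over all other cells of -1.67 and -1.47. Pooled over mice, the cells compared were spread differently over clusters by matrix. The 2 largest were clusters 9 and 3 in collagen and 10 and 3 in Matrigel on day 0, 20 and 15 against 1 and 24 on day 3, and 16 and 17 against 17 and 11 on day 5. Some of these clusters came mainly from 1 mouse. Mouse 4 gave 412 of the 621 cells of cluster 10, 326 of 426 of cluster 1 and 136 of 146 of cluster 24. Mouse 3 gave 387 of 482 of cluster 20, whereas others, such as cluster 3, drew on several mice. The pooled spread thus also depends on how many cells each mouse gave, and it was not compared within mice. A difference between the matrices may reflect the mix of cells as well as a change within them. A further 57 cells that carried a mouse label clustered with the 4T1 line, 26 of them from collagen and 16 from Matrigel on day 0.

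Vim, which encodes the mesenchymal intermediate filament vimentin (ENSMUSG00000026728, GRCm38 chromosome 2, 13573927 to 13582826, plus strand), was detected in a larger mean share of cells in collagen on each day, and no difference passed its exact test. After thinning each cell to 2000 UMIs, 16.89% ± 2.51 (SD, n = 4 mice) of collagen cells and 11.03% ± 2.80 (n = 4) of Matrigel cells had a Vim UMI on day 0, a difference of 5.86 percentage points (exact two-sided permutation test, p = 0.0571, smallest possible 0.0286). The difference had this sign in all 4 mice, and paired by mouse its exact permutation p was 0.125, the smallest that 4 pairs can give. On day 3 the shares were 31.9% ± 13.5 and 14.9% ± 4.04 (difference 17.0 points, exact permutation p = 0.114). Mouse 3 went the other way on that day (15.7% and 16.35%), and paired by mouse the exact permutation p was 0.25. On day 5 they were 50.3% ± 13.9 (n = 3) and 18.5% ± 7.08 (n = 2), a difference of 31.8 points with an exact permutation p of 0.20, the smallest that 3 against 2 can give. Mouse 1 had the highest collagen share on that day (66.34%) and no Matrigel share, so this difference also includes one between mice. Paired in mice 2 and 3 alone, the difference was 23.75 points (exact permutation p = 0.5, the smallest possible). Counting only cells with 2 or more UMIs, the differences were 5.71 points on day 0 and 15.1 points on day 3, each with an exact permutation p of 0.0286. Without the 57 mouse-labelled cells of the 4T1 cluster the day 0 difference was 4.02 points (exact permutation p = 0.114). Without thinning, the shares were 39.6% and 36.1% on day 0, 62.0% and 48.4% on day 3, and 84.2% and 79.0% on day 5. The 4T1 cells, a vimentin-rich line, had a Vim UMI in 91.8%, 82.0% and 84.2% of thinned cells on the 3 days.

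Krt14, a basal keratin (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548, minus strand), was detected in 52.2% of collagen and 59.0% of Matrigel cells on day 0 (difference -6.74 points, exact permutation p = 0.314). It was lower in collagen in all 4 mice, and paired by mouse the exact permutation p was 0.125, the smallest possible. The differences were -0.28 points on day 3 (exact permutation p = 0.914) and 13.3 points on day 5 (p = 0.20, the smallest possible in this permutation test). Without thinning, the day 0 difference was -9.72 points with an exact permutation p of 0.0286, and that of day 5 was -1.13 points. In macrophage-like cells of the day 0 pool, which should lack the gene, 2.34% of cells (4 of 171, exact 95% interval 0.64 to 5.88%, median 14486 UMIs) had a Krt14 UMI after thinning, and in 4T1 cells 15.3%. Macrophages express Vim (50.3% of the same cells), so no cell class gave a background for Vim.

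**Figure D1:**
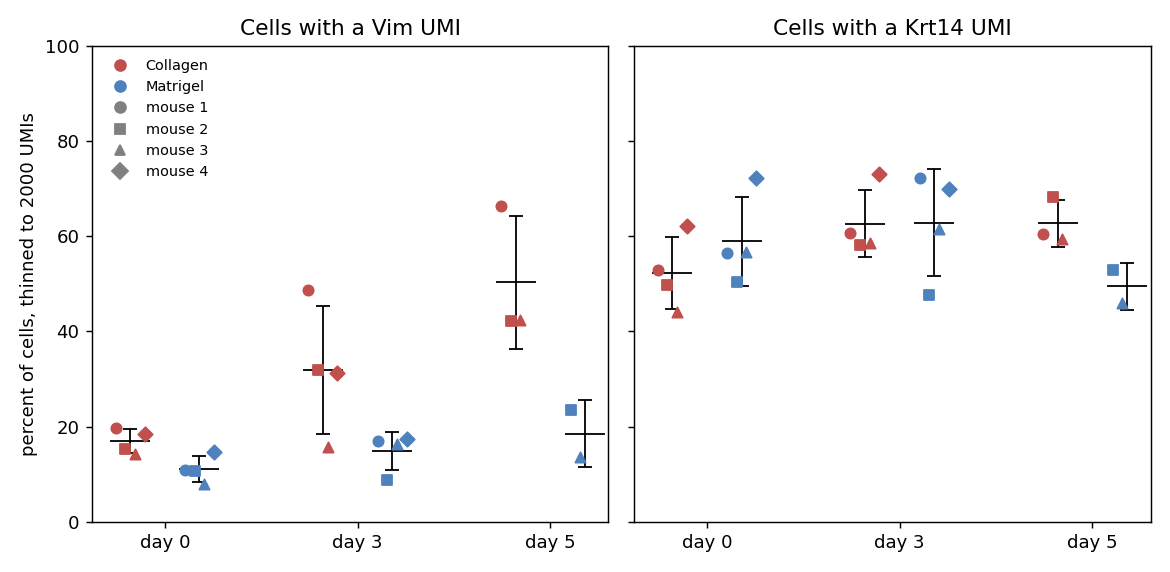
Percent of cells with at least 1 Vim UMI (left) or Krt14 UMI (right) after thinning to 2000 UMIs per cell, by day and matrix. Points are mice, bars the mean and SD over mice. Mean Vim shares on day 5 were 50.3% in collagen (mice 1, 2 and 3) and 18.5% in Matrigel (mice 2 and 3).

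On day 0, 10 of 19 interferon response and 6 of 12 antigen presentation genes were higher in collagen than in Matrigel, and 5 of 12 oxidative stress genes were lower. Psmb8, a subunit of the immunoproteasome (chromosome 17, 34197721 to 34201454), averaged 206 ± 29.8 CPM (SD, n = 4) in collagen and 63.2 ± 10.8 CPM (n = 4) in Matrigel (log2 fold change 1.71, SE 0.20, adjusted p = 0.000163). Hmox1, the heme oxygenase induced by oxidative stress (chromosome 8, 75093621 to 75100589), averaged 118 ± 19.5 and 985 ± 320 CPM (log2 fold change -3.07, SE 0.43, adjusted p = 0.000577). In all, 547 genes were higher and 380 lower in collagen among 13184 tested, and with the mouse as a block 1648 and 1559. Of 19 interferon response genes, 10 were higher and none lower (14 adjusted over the list alone), among them Zbp1 (log2 fold change 2.90), Oasl2 (2.45), the transcription factor Irf7 (2.44, SE 0.60, 49.3 ± 20.9 against 9.14 ± 4.67 CPM) and Isg15 (1.76). The set test of the list gave an adjusted p of 4.91e-13, and adjusted p = 0.0774 with an estimated correlation (0.0348 without the 57 cells). Of 12 antigen presentation genes, 6 were higher (9 adjusted over the list alone), including Psmb9 (1.52) and the peptide transporter subunit Tap2 (1.41), with adjusted p = 0.029 with an estimated correlation. Ifitm3 (2.09), outside the lists, and the chemokine Ccl5 (2.45) were higher in all 4 mice. Of 12 oxidative stress genes, 5 were lower and none higher (9 adjusted over the list alone). They included Srxn1 (-1.71) and the glutathione synthesis genes Gclm (-1.66, 217 ± 59.0 against 687 ± 193 CPM) and Gclc (-1.42). The set test gave an adjusted p of 1.16e-11, and adjusted p = 0.0635 with an estimated correlation (0.0348 without the 57 cells).

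Members of 6 further lists passed on day 0, and none of these lists passed with an estimated correlation (adjusted p = 0.257 for basement membrane genes and adjusted p = 0.68 for each of the others). Of 20 cholesterol synthesis genes, 4 were higher in collagen (7 adjusted over the list alone), such as Mvk (1.19) and Fdps (0.85). Among 21 hypoxia and glycolysis genes, 2 were higher (3 adjusted over the list alone; 7 with the block), Bnip3 (1.86) and the kinase Pdk1 (1.54), the latter with an adjusted p of 0.0538 without the 57 cells. Of 14 basement membrane genes 2 were higher (3 adjusted over the list alone; 7 with the block), Agrn (0.97) and Col7a1 (0.96), and of 16 unfolded protein response genes 4 were higher and 1 lower (4 and 1 adjusted over the list alone), including Pdia4 (0.84), Hsp90b1 (0.66) and Dnajb9 (-0.94). Of 19 mitotic genes only Ccnb2 passed (1.51), against 10 with the block. Of 15 mesenchymal genes, 3 were higher (5 adjusted over the list alone; 6 with the block): Vim (1.90, SE 0.48, 766 ± 479 against 205 ± 81.5 CPM), Lgals1 (1.48) and Fbn1 (3.01, below 5 CPM in both matrices). Without the 57 cells Vim had a log2 fold change of 1.16 (adjusted p = 0.143; 0.0612 with the block). Of the 12 state markers chosen in advance, Vim alone passed, and the smallest adjusted p of the other 11 was that of Cdh1, E-cadherin (-0.75, adjusted p = 0.0897, and 0.000379 with the block). The block also brought Krt8 (-0.76), Trp63 (1.77) and Mki67 (0.55; adjusted p = 0.111 without the 57 cells) past the threshold. Of the markers of other cell types, 1 of 4 endothelial markers was higher, and no fibroblast, pericyte, macrophage, neutrophil or dendritic marker passed. Cx3cr1 was higher by 4.67 on the log2 scale, and by 3.60 (adjusted p = 0.0852) without the cluster of few UMIs. Leaving out mouse 1, 2, 3 or 4 gave 132, 81, 267 or 799 genes, of which 131, 78, 251 or 565 were among the 927. Of the 35 passing genes considered here 13, 7, 18 or 30 kept their call. The limma test on log values averaged over cells, which differs in both summary and test, gave 49 higher and 227 lower genes.

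On day 3, 22 genes were higher and 5 lower in collagen, and those higher included the matrix protein genes Postn, Fbln2 and Col7a1. Postn, the matricellular protein periostin, averaged 38.5 ± 21.4 CPM (n = 4) in collagen and 1.36 ± 0.67 CPM (n = 4) in Matrigel (log2 fold change 4.98, SE 0.93, adjusted p = 0.0275). Fbln2, the extracellular matrix protein fibulin-2, averaged 338 ± 77.7 and 118 ± 25.2 CPM (1.52, SE 0.22, adjusted p = 0.00318). Also higher in all 4 mice were the lactate transporter Slc16a3 (2.50), Nt5dc2 (1.38), the actin-binding Cotl1 (1.12), the integrin activator Fermt1 (1.09), the TGF-beta target Pmepa1 (1.07, 661 ± 80.6 against 315 ± 75.0 CPM), Chst2 (0.92), Nav2 (0.76) and Ddx41 (0.64). Of 15 mesenchymal genes, Postn alone passed (7 adjusted over the list alone; 8 with the block), and the list was higher in collagen with adjusted p = 5.88e-10, and adjusted p = 0.0363 with an estimated correlation. No member of the 20 matrix proteases and inhibitors or the 16 matrix receptors passed (1 each adjusted over the list alone; 5 and 2 with the block), and both lists were higher (adjusted p = 0.0261 and adjusted p = 0.0363 with an estimated correlation). Collagen VII (Col7a1, 1.45) was the basement membrane gene that passed of 14, and the prolyl hydroxylase P4ha1 (1.29) the hypoxia gene of 21, with 4 in each list with the block, and adjusted p = 0.104 and adjusted p = 0.153 with an estimated correlation. Actin and contractility genes (16) and basal genes (16) had no member passing (5 and 4 adjusted over the list alone), with adjusted p = 0.0854 and adjusted p = 0.0786 with an estimated correlation.

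None of the 12 state markers passed on day 3, with Vim closest (1.86, SE 0.48, adjusted p = 0.134), and 3 passed with the block, Vim (1.65), Fn1 (1.26) and Cdh1 (-0.44). The block also brought in Mmp14 (1.44, adjusted p 5.80e-05), Sdc1 (0.66) and Tagln (5.11), each at an adjusted p of 0.0559 or more without it. With the block, 576 genes passed. Fibroblast markers lay higher in collagen as a list (median log2 fold change 1.26 over 5 genes, adjusted p = 0.00427, and adjusted p = 0.0854 with an estimated correlation), with no member passing. Without mouse 1, 2, 3 or 4 the count was 1, 3, 7 or 58, and 1, 2, 3 or 9 of the 12 passing genes considered here kept their call. A fit of the 2 groups alone gave 0 genes in edgeR, against 1302 at an unadjusted p under 0.05 in the fit of all groups, 182 by DESeq2 and 14, all higher, by limma on log averages over cells.

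On day 5, integrin, actin and TGF-beta target genes were higher in collagen, and 43 genes were higher and 17 lower. Itga2, the collagen-binding integrin alpha 2 subunit (chromosome 13, 114833081 to 114932100), averaged 112 ± 40.8 CPM (n = 3) in collagen and 14.8 ± 4.34 CPM (n = 2) in Matrigel (log2 fold change 2.94, SE 0.62, adjusted p = 0.0414). Of 16 matrix receptors 4 were higher and none lower (6 adjusted over the list alone), Itga2, Itga5 (3.08, 19.2 ± 3.23 against 2.28 ± 0.18 CPM), Itgav (1.11) and Sdc1 (1.04), with adjusted p = 0.00471 with an estimated correlation. Of 16 actin and contractility genes 2 were higher (11 adjusted over the list alone; 11 with the block), filamin A (Flna, 1.04) and Tagln2 (0.98), with adjusted p = 0.0138 with an estimated correlation. Of 15 TGF-beta targets, Pmepa1 (1.82, SE 0.25, 704 ± 141 against 200 ± 37.1 CPM) and the inhibitory Smad7 (1.63) were higher (5 higher and 1 lower adjusted over the list alone; 6 higher with the block), with adjusted p = 0.0244 with an estimated correlation. Matrix proteases and inhibitors (20 genes) and mesenchymal genes (15 genes) had no member passing (8 and 7 adjusted over the list alone; 6 and 6 with the block), and both lists were higher, with adjusted p = 0.00143 and adjusted p = 0.0244 with an estimated correlation. Plau was at 18.4 ± 2.97 and 5.03 ± 0.29 CPM (adjusted p = 0.0886; 0.007 with the block). Outside the lists, Fxyd5 (2.81), thymosin beta 4 (Tmsb4x, 2.19), Tnnt2 (2.12), Cotl1 (1.61), Fermt1 (1.60) and Tuba1a (1.60) were higher. Lower in collagen were the Wnt inhibitor Sfrp1 (-2.06), the homeobox genes Irx1 (-1.52, 115 ± 7.42 against 329 ± 23.1 CPM) and Irx2 (-1.01), the splicing regulator Rbm47 (-1.21) and Wwc1 (-1.14).

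No state marker passed on day 5; Fn1 was closest (1.97, adjusted p = 0.0993), and Fn1 (2.13), Vim (2.02) and Cdh1 (-0.70) passed with the block, under which 828 genes passed. Fibroblast markers had a median of 2.34 over 5 genes (adjusted p = 0.0288, adjusted p = 0.0521 with the block, and adjusted p = 0.247 with an estimated correlation), again with no member passing. Every call on this day rests on 2 Matrigel mice with 51 and 38 cells. These were mice 2 and 3, set against mice 1, 2 and 3 in collagen. Without mouse 1, 2 or 3 the count was 1, 0 or 0, with 1, 0 and 0 of the 21 passing genes considered here kept. Without mouse 4, which has no day 5 sum and enters only through the shared spread, it was 276. Without the 57 cells, 16 of the 21 kept their call; Tmsb4x, Tnnt2, Sdc1, Sfrp1 and Irx2 then lay between adjusted p = 0.0515 and adjusted p = 0.0649. The limma test on log averages over cells gave 46.1% higher calls, against 71.7%.

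The matrix difference itself changed between day 0 and day 3 for 4 genes and between day 0 and day 5 for 157, tested as an interaction in which the batch of each day cancels. All 4 genes of day 3 moved towards Matrigel: the mevalonate kinase Mvk (-1.86, SE 0.28, adjusted p = 0.0318), Psmb8 (-1.59), Pgpep1 (-1.22) and Ndufaf3 (-0.94), of which Pgpep1 was named after its value was seen. Cholesterol synthesis genes (1 of 20; 7 adjusted over the list alone) and antigen presentation genes (1 of 12; 6 adjusted over the list alone) moved towards Matrigel as lists (adjusted p 1.45e-09 and 2.63e-07, and adjusted p = 0.241 and adjusted p = 0.238 with an estimated correlation). An unadjusted p under 0.05 was reached by 1435 genes, the block gave 704, DESeq2 161, and leaving out mouse 1, 2, 3 or 4 gave 0, 0, 0 or 1, with none of the 4 genes kept. With DESeq2's size factors 15 genes passed, 26.7% of them towards collagen, and the limma test on log averages over cells gave 2 genes, both towards collagen. No state marker passed (Fn1 closest, 1.52, adjusted p = 0.275; 0.0365 with the block).

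By day 5, 63 genes had moved towards collagen and 94 towards Matrigel. Mouse 4 and, in Matrigel, mouse 1 entered no day 5 sum, so without the block this change also includes differences between mice. Hmox1 moved by 3.77 (SE 0.71, adjusted p = 0.0187), from 985 CPM in day 0 Matrigel to 60.6 ± 22.8 in collagen (n = 3) and 36.9 ± 14 in Matrigel (n = 2). Of 16 matrix receptors 3 moved towards collagen (6 adjusted over the list alone), Itga5 (2.76), the hyaluronan receptor Cd44 (1.63) and Itgav (0.91), with adjusted p = 0.055 with an estimated correlation. Actin genes followed with 2 of 16 (8 adjusted over the list alone), Flna (1.16) and the myosin heavy chain Myh9 (0.95), with adjusted p = 0.0887 with an estimated correlation, and 2 of 20 proteases and inhibitors did (3 adjusted over the list alone), among them the urokinase Plau (2.52), with adjusted p = 0.0543 with an estimated correlation. Smad7 (1.77), the AP-1 factor Fosl1 (2.67), Klf4 (2.10), Fxyd5 (2.45) and Tmsb4x (2.47) moved the same way. Towards Matrigel moved Ifitm3 (-2.56), Ifitm2 (-1.90), the desaturase Scd1 (-2.09), Irx1 (-1.72) and Mvk (-1.58). The block gave 1809 genes, and without mouse 1, 2, 3 or 4 there were 0, 0, 0 or 254, with 0, 0, 0 and 15 of the 17 genes considered here kept. Without the 57 cells 14 of the 17 kept their call, with Tmsb4x, Klf4 and Scd1 between adjusted p = 0.052 and adjusted p = 0.0627. No state marker passed, with Fn1 closest (2.35, adjusted p = 0.065). Fn1 (2.47, adjusted p = 0.00616), Krt8 (1.25) and Mki67 (-1.15) passed with the block.

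**Figure D2:**
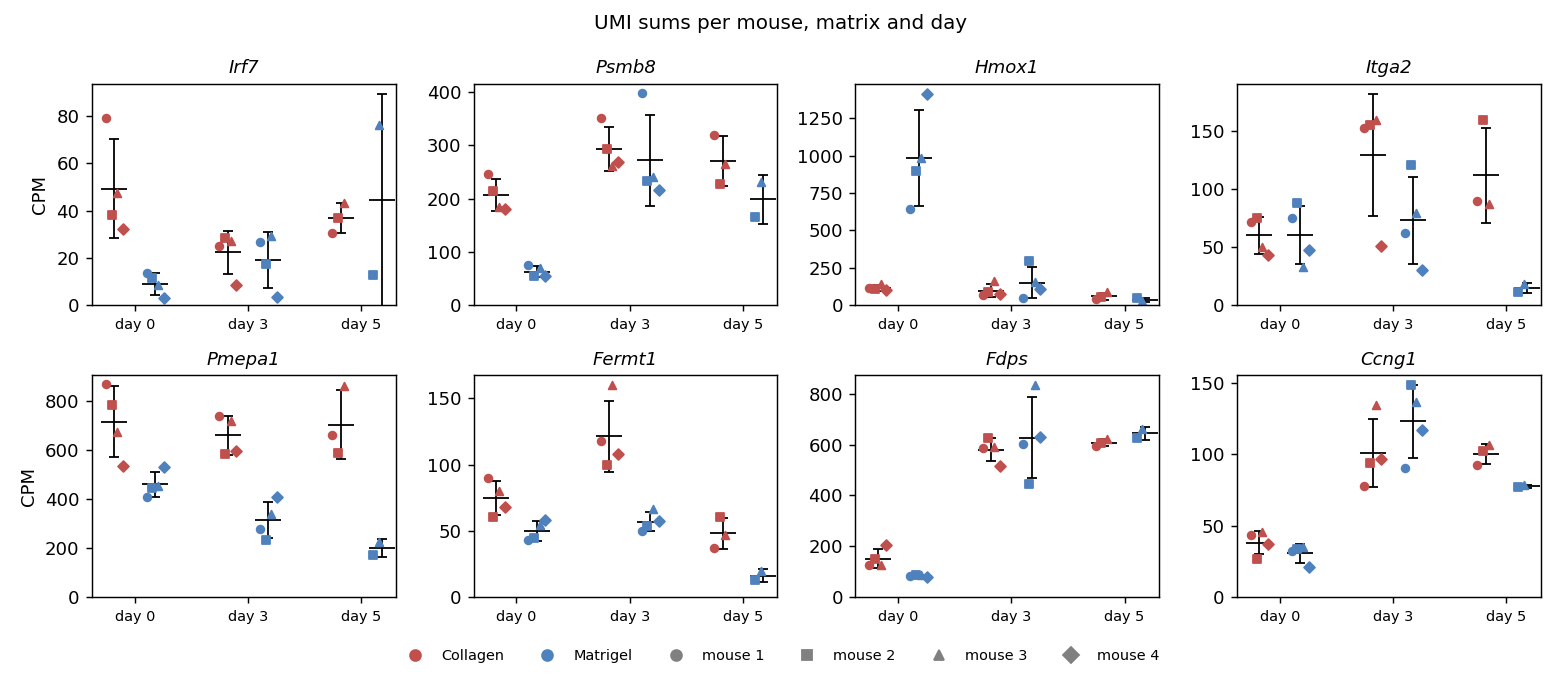
CPM of 8 genes per mouse, matrix and day, with mean and SD over mice; each panel has its own axis starting at 0. Hmox1 averaged 985 CPM in Matrigel against 118 CPM in collagen on day 0, and Itga2 averaged 112 CPM in collagen against 14.8 CPM in Matrigel on day 5.

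In collagen, 16 of 20 cholesterol synthesis and 12 of 15 oxidative phosphorylation genes were higher on day 3 than on day 0, and 4 of 12 heat shock and 5 of 19 interferon response genes were lower. None of these 4 lists passed with an estimated correlation. The farnesyl diphosphate synthase Fdps rose from 151 ± 36.6 to 580 ± 45.4 CPM (n = 4 each; log2 fold change 1.94, SE 0.17, adjusted p = 2.55e-07), and Hspa1a fell from 597 ± 445 to 24.6 ± 3.36 CPM (-4.59, SE 0.58, adjusted p = 2.55e-05). In total 1230 genes rose and 1351 fell, and 2405 and 2570 with the block. Of 20 cholesterol synthesis genes 16 rose and none fell (17 adjusted over the list alone), including Nsdhl (1.43), Fdft1 (1.14) and Mvk (1.22), with adjusted p = 1.30e-14 for the list and adjusted p = 0.246 with an estimated correlation. In the 4T1 cells of the same pools these 4 genes went the other way, by -1.23, -1.45, -1.79 and -1.11. Of 15 nuclear oxidative phosphorylation genes 12 rose (13 adjusted over the list alone), with Cox7b (1.10), Ndufa2 (1.08) and Cox7a2 (1.03) leading and adjusted p = 0.204 with an estimated correlation; in 4T1 they moved by 0.45, 0.81 and 0.16. Of 13 p53 targets 5 rose (7 adjusted over the list alone; 8 with the block), among them the cyclin Ccng1 (38.2 ± 8.25 to 101 ± 23.9 CPM), Phlda3 (1.42), Zmat3 (1.35) and Bax (1.12), with adjusted p = 0.246 with an estimated correlation.

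Of 12 heat shock genes 4 fell in collagen (6 adjusted over the list alone), including Hspa1b (-2.90) and Hsp90aa1 (-0.59), with adjusted p = 0.581 with an estimated correlation; without the cluster of few UMIs, Hspa1a changed by -3.69 and Hspa1b by -2.08. Of 19 interferon response genes 5 fell (5 adjusted over the list alone; 13 lower with the block), such as Cxcl10 (-3.48) and Oasl2 (-1.47), and of 19 immediate early genes 4 fell (4 adjusted over the list alone; 8 lower with the block), such as Atf3 (-1.60) and Dusp1 (-1.32), each with adjusted p = 0.945 with an estimated correlation. Among YAP targets 4 of 12 fell (4 adjusted over the list alone), including F3 (-1.90), Ctgf (-1.84) and Cyr61 (-1.16), and 4T1 cells showed -0.45, -2.33 and -1.40. Ccl5 (-3.37), Cx3cr1 (-5.11), hexokinase 2 (Hk2, -2.56) and the amino acid transporter Slc7a5 (-2.72) also fell, and gamma-synuclein (Sncg, 4.12) rose. Of 15 mesenchymal genes 2 fell and 1 rose (2 and 1 adjusted over the list alone), and the 2 that fell were S100a4 (-1.99) and Loxl2 (-2.43); without the 57 cells S100a4 changed by -0.05 (adjusted p = 0.935), and 3 rose and 1 fell (3 and 1 adjusted over the list alone). None of the 12 state markers passed (Krt14 closest, 0.88, adjusted p = 0.0513), and Krt14 (0.89; adjusted p = 0.0645 without the 57 cells) and Cdh1 (-0.65) did with the block. Vim changed by -0.29 (adjusted p = 0.715) with the 57 cells and rose without them, from 145.9 ± 84 to 632.1 ± 436 CPM (n = 4 each; 2.11, SE 0.48, adjusted p = 0.00396). Macrophage and fibroblast markers had no member passing, 1 of 3 dendritic and 1 of 3 neutrophil markers fell, and of 4 endothelial markers 1 rose and 1 fell. When the change of the 4T1 cells was subtracted, 403 genes passed, 233 of them also called without it, and 6 of the 34 genes considered here kept their call; 15% of the 957 genes changed at least 2-fold had moved in 4T1 by at least 50% as much in the same direction. Without mouse 1, 2, 3 or 4 the count was 1339, 992, 1538 or 3016. The limma test on log averages over cells gave 75.4% higher calls, against 47.7%.

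In Matrigel the day 3 cells differed from day 0 in more genes, 2555 higher and 2602 lower (7223 with the block). These included members of stress, growth factor and mitotic lists, none of which passed as a list with an estimated correlation. Hmox1 fell from 985 ± 320 to 152 ± 105 CPM (-2.69, SE 0.42, adjusted p = 6.66e-05, n = 4 each), and Fdps rose from 83.8 ± 4.70 to 628 ± 160 CPM (2.91, SE 0.17, adjusted p = 1.11e-09). Of 20 cholesterol synthesis genes 17 rose (17 adjusted over the list alone), led by Mvk (3.08), Fdps and Mvd (2.67), and of 15 oxidative phosphorylation genes 13 rose (14 adjusted over the list alone), with Cox7b (1.43) and Ndufs6 (1.20), each with adjusted p = 0.157 with an estimated correlation. Of 19 mitotic genes 10 rose and none fell (10 adjusted over the list alone; 15 with the block), including Ccnb2 (2.40), Plk1 (1.67), Cenpa (1.19) and Mki67 (0.87), with adjusted p = 0.856 with an estimated correlation. In 4T1 cells Ccnb2, Plk1, Cenpa and Mki67 changed by -1.18, -1.18, -0.97 and -1.48. Of 13 p53 targets 6 rose (6 adjusted over the list alone), such as Ccng1 (2.01) and Zmat3 (1.96), with adjusted p = 0.619 with an estimated correlation. Antigen presentation genes went both ways, 3 higher and 1 lower of 12 (3 and 1 adjusted over the list alone), with Psmb8 up by 2.10 (SE 0.20).

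Of 19 immediate early genes, 12 fell in Matrigel and none rose (13 adjusted over the list alone), including Dusp1 (-2.92), Rhob (-2.25) and Klf6 (-1.80), with adjusted p = 0.524 with an estimated correlation. Heat shock genes fell in 9 of 12 cases (9 adjusted over the list alone), from Hspa1a (-4.73) to Dnajb1 (-0.82), with adjusted p = 0.245 with an estimated correlation. Of 14 FGF and ERK response genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), among them Fosl1 (-2.45), Spry2 (-1.87) and Dusp6 (-1.25), with adjusted p = 0.619 with an estimated correlation. YAP targets fell in 5 of 12 cases (5 lower and 1 higher adjusted over the list alone), with F3 (-3.00), Ctgf (-3.03) and Cyr61 (-2.21), and oxidative stress genes in 5 of 12, with 1 higher (5 and 1 adjusted over the list alone), including Gclc (-1.05), each with adjusted p = 0.84 with an estimated correlation. The urokinase Plau (-1.45) and its receptor Plaur (-2.94) fell. Of the 12 state markers 5 passed: Krt5 (2.46, in 3 of 4 mice) and Mki67 rose, and Cdh1 (-0.92), Epcam (-0.55) and Fn1 (-1.05) fell, while the next smallest adjusted p was that of Snai2 (0.0789). The block added Snai2 (2.19), Trp63 (1.26) and Krt8 (-0.47). Vim changed by -0.25 (adjusted p = 0.707) with the 57 cells, and rose by 1.36 (SE 0.47, adjusted p = 0.0285) without them. Among markers of other cell types, 2 of 3 dendritic, 1 of 3 neutrophil and 1 of 6 macrophage markers fell, of 4 endothelial markers 1 rose and 1 fell, 1 of 4 pericyte markers rose, and no fibroblast marker passed. When the change of 4T1 was subtracted, 1330 genes passed, 1075 of them also called without it, and 15 of the 39 genes considered here kept their call. Of the 2288 genes changed at least 2-fold, 9.57% had moved in 4T1 by at least 50% as much in the same direction. Leaving out mouse 1, 2, 3 or 4 gave 3636, 3288, 3838 or 4965 genes.

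In both matrices some genes moved by at least 3 on the log2 scale between the day 0 and day 3 pools, and 4T1 cells went in the same direction for those named here. Nme2 rose by 5.41 in collagen and 5.61 in Matrigel (5.15 in 4T1), and Cdk2ap1 fell by 3.10 and 3.09 (-2.66 in 4T1). These genes share sequence with a neighbouring or near-identical gene, so their counts are uncertain. Hist1h2ap, one of a family of near-identical histone genes, rose by 4.73 and 5.63 (2.18 in 4T1).

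From day 3 to day 5 in collagen 90 genes rose and 62 fell. With the mouse as a block 612 rose and 778 fell, so the larger side depended on the design. Mouse 4 had a sum on day 3 and none on day 5, so without the block this step also includes differences between mice. Hist1h1b, a linker histone whose family is uncertain in counting, went from 156 ± 41.1 (n = 4) to 28.8 ± 2.81 CPM (n = 3; -2.43, SE 0.37, adjusted p = 0.00128), Hist1h1e changed by -1.85 and Hist1h2ae by -1.71, while 4T1 cells showed 0.38, -1.50 and -0.24. Fermt1 (-1.33) and Bspry (-1.07) fell as well. Among genes that rose were the adaptor Nck2 (1.56), Hypk (1.46), the tubulin Tuba1a (1.41), Etfb (1.37), caveolin 2 (Cav2, 1.17) and the receptor Notch2 (1.08), of which Tuba1a rose by 2.94 in 4T1. Of 15 oxidative phosphorylation genes Cox7b fell (-0.62; 9 lower adjusted over the list alone, 8 with the block), with adjusted p = 0.509 with an estimated correlation. Of 21 hypoxia and glycolysis genes none passed (6 higher adjusted over the list alone, 8 with the block), with the same estimated-correlation value, adjusted p = 0.509. Among 13 mitochondrially encoded genes, mt-Nd3 rose (2.04; 2.05 in 4T1) and mt-Nd4l fell (-1.24; -1.02 in 4T1), and 3 rose and 2 fell adjusted over the list alone. Cdk2ap1 (2.66; 1.71 in 4T1) went back part of the way. No state marker passed, Epcam being closest (-0.61, adjusted p = 0.0982; 0.0102 with the block), and no marker of another cell type passed. The block gave 1390 genes and the subtraction of 4T1 117 (1 of them also called without it), with none of the 15 genes considered here kept; 51.9% of the 54 genes changed at least 2-fold had moved in 4T1 by at least 50% as much. Without mouse 1, 2, 3 or 4 the counts were 23, 25, 26 and 349, and the limma test on log averages over cells gave 81.4% higher calls, against 59.2%.

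From day 3 to day 5 in Matrigel 192 genes rose and 138 fell, with 4 of 16 Notch and Wnt genes higher and the integrin genes Itga2, Itga5 and Itgb1 lower. With the mouse as a block 772 rose and 904 fell, so the larger side depended on the design. The day 5 sums came from mice 2 and 3 and those of day 3 from all 4 mice. Without the block this step therefore also includes differences between mice. Of 16 Notch and Wnt genes 4 rose and none fell (8 adjusted over the list alone; 7 with the block), with adjusted p = 0.0218 with an estimated correlation. Hes1 rose by 1.67 (SE 0.30, 57.5 ± 13.2 CPM in 4 sums to 182 ± 103 CPM in 2, and by 3.51 in 4T1), Hey1 by 3.02 and Tcf7 by 1.33, and the stem cell marker Lgr5 was at 6.85 ± 4.24 CPM on day 5 with no UMI in the 4 sums of day 3. Of 7 milk protein genes 2 rose (2 adjusted over the list alone), Mfge8 (1.78) and Trf (4.56), with adjusted p = 0.516 with an estimated correlation. The hypoxia genes Egln3 (3.13) and Aldoc (1.67) were 2 of 21 (6 adjusted over the list alone; 12 with the block), with adjusted p = 0.37 with an estimated correlation, and the ERK response genes Dusp6 (1.61, SE 0.18) and Etv5 (1.46) were 2 of 14 (5 higher and 2 lower adjusted over the list alone). Sfrp1 (1.69), ceruloplasmin (Cp, 1.96) and Sod3 (2.02) rose, and so did the interferon gene Rsad2 (5.01), which changed by -0.90 without mouse 2. Of 16 matrix receptors Itga2 (-2.32), Itga5 (-2.14) and Itgb1 (-0.93) fell (6 lower and 2 higher adjusted over the list alone), and of 13 p53 targets Cdkn1a (-1.96) and Phlda3 (-1.09) did (5 adjusted over the list alone; 6 with the block), with adjusted p = 0.51 and adjusted p = 0.334 with an estimated correlation. The activin subunit Inhba (-2.11) and Smad7 (-1.01), of 15 TGF-beta targets, Fxyd5 (-2.85) and Fermt1 (-1.84) fell too. No state marker passed (Krt8 closest, adjusted p = 0.374; 0.0167 with the block), and no marker of another cell type passed. The block gave 1676 genes and the subtraction of 4T1 82 (7 of them also called without it), with 1 of 26 genes considered here kept. Without mouse 1, 2, 3 or 4 there were 138, 14, 33 or 610 genes, with 15, 4, 7 and 22 of the 26 kept, and a fit of the 2 groups alone gave 2. Without the 57 cells Cp, Sfrp1, Sod3 and Itgb1 lay between adjusted p = 0.0583 and adjusted p = 0.0702. The limma test on log averages over cells gave 90% higher calls, against 58.2%.

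Tumour cells of mice 1, 2 and 3 expressed a stretch of chromosome 6 above the 4T1 cells of the same pool, a pattern looked for after the data were seen. Over 29 genes between 138140316 and 147264183 (GRCm38), from Mgst1 to Pthlh, the median log2 ratio over 4T1 on day 3 was 2.74 in mouse 1, 2.33 in mouse 2 and 1.72 in mouse 3, and 0.07 in mouse 4. Genes of the segment such as Golt1b, Ldhb, Etnk1 and Cmas were named after their values were seen.

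**Figure D3:**
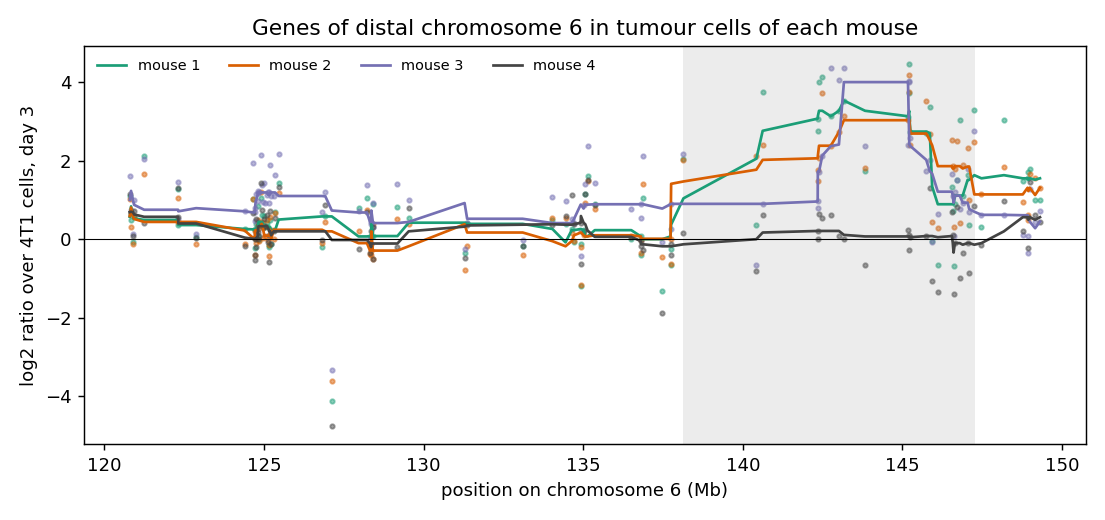
Log2 ratio of expression in day 3 tumour cells over day 3 4T1 cells, by position on chromosome 6 in Mb, 1 colour per mouse. Dots are genes, lines the running median of 9 genes, and grey marks the segment shared by mice 1, 2 and 3. The median ratio in the segment was 2.74, 2.33 and 1.72 in mice 1, 2 and 3 and 0.07 in mouse 4.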

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

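The tests on the 57 cells were chosen only after the result was seen, while the test of other splits was set beforehand. Among 311 groups of 4 mice, 24 (7.7%) held a mouse set apart from the other 3 by a gap large relative to the range. About 1 in 20 groups of independent normal values would. The rule has no minimum size or count and the genes are not independent, so the share cannot be read as an excess. In collagen on day 0 these were Tap2 in mouse 4 (36.6 CPM, others 61.2 to 63.8), Agrn (20.1, others 27.8 to 29) and Col7a1 (10.9, others 16.1 to 17.1) in mouse 3, Ccnb2 in mouse 4 (73.5, others 48.7 to 49.7), Hsp90aa1 (2216.9, others 1640.5 to 1689.9) and F3 (121.6, others 70.0 to 75.8) in mouse 2, and Itgav in mouse 1 (41.5, others 39.0 to 39.2). In Matrigel on day 0 they were Lce3c in mouse 1 (187.0, others 0.2 to 5.6), Hp (1.7, others 0.1 to 0.3) and Igkc (901.1, others 4.3 to 9.2) in mouse 3, Dcpp1 in mouse 2 (1452.3, others 0.3 to 37.6) and Tmsb4x in mouse 4 (3576.5, others 1574.7 to 1854.0). In collagen on day 3 they were Slc16a3 in mouse 1 (153.4, others 58.0 to 60.6), Cx3cr1 in mouse 4 (3.8, others 0.9 to 1.0), Atf3 (45.3, others 27.9 to 30.4) and Ctgf (16.4, others 27.5 to 28.0) in mouse 3, and the share of Krt14 positive cells in mouse 4 (73.04%, others 58.17 to 60.61%). In Matrigel on day 3 they were Col7a1 in mouse 4 (7.4, others 5.0 to 5.3), Spry2 (48.9, others 17.1 to 21.6) and Hist1h1b (110.6, others 276.8 to 291.5) in mouse 2, Psmb8 (398.3, others 215.7 to 239.8), Hp (246.5, others 0.2 to 32.1) and Dcpp1 (0.6, others 0) in mouse 1, and the share of Vim positive cells in mouse 2 (8.84%, others 16.35 to 17.3%). The single mice of Lce3c, Dcpp1 and Igkc carry most of the signal of these genes. Of the 8246 UMIs of Igkc, 7681 (93.1%) came from 1 cell.

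The matrix difference differed between days in the interaction test for 4 genes by day 3, Mvk (-1.86), Psmb8 (-1.59), Pgpep1 (-1.22) and Ndufaf3 (-0.94), and for 157 by day 5. By day 5 they included Hmox1 (3.77), Fosl1 (2.67), Plau (2.52), Tmsb4x (2.47), Fxyd5 (2.45), Klf4 (2.10), Cd44 (1.63), Itga5 (2.76), Itgav (0.91), Flna (1.16), Myh9 (0.95), Smad7 (1.77), Ifitm3 (-2.56), Ifitm2 (-1.90), Scd1 (-2.09), Irx1 (-1.72) and Mvk (-1.58). Of 100 splits of the sums for the change by day 3, drawn with the real one included, 5 gave as many genes as the real 4, the highest other giving 181, so chance cannot be excluded for this count. A split that calls 181 genes points to a structure of the samples: it sets 1 collagen day 3 sum with 4 Matrigel day 0 and 3 Matrigel day 3 sums, and so largely parts the matrices. Among the 11 splits that part as many pairs of a mouse, the highest other count was 48.

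Cells outside the comparisons also carried signal. Vim was detected in 91.84%, 81.96% and 84.21% of 4T1 cells on days 0, 3 and 5, and 337 cells of the tumour cultures lay in clusters named as other cell types.

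A further 57 cells with a mouse label lay in the cluster of the 4T1 line. Over 53 genes high in 4T1 and not used for clustering, their median level was 91.6% of that of annotated 4T1 cells (3088 against 3372 CPM). This is as 4T1 cells or doublets with them would give, but the 57 cells were picked by clustering with 4T1. Epithelial-like cells, taken here with the unnamed clusters other than that of few UMIs, had 268 CPM. Over 203 genes high in these tumour cells the 57 cells had 10.1% of their level (1851 against 18349 CPM). The matrix design would offer another explanation, tumour cells in a mesenchymal state. Such cells could also have lost genes chosen as higher in tumour than in 4T1 cells, so these values cannot separate the explanations. A candidate explanation for most of the 57 cells is 4T1 cells or doublets under a mouse barcode. In the tumour-high genes 23 of the 57 lay above 95% of 4T1 cells, and which cells are doublets was not tested. Igkc was among the leading genes of this cluster. The cell with 7681 of its UMIs had 661 CPM of the 4T1-high genes, so the explanation need not hold for every cell. In collagen on day 0, 26 such cells of 939 (2.77%) held 12.4% of the UMIs and 76.2% of the Vim UMIs. The load was uneven, and in mouse 4 of that group 11 such cells held 30.7% of the UMIs and 95.7% of the Vim UMIs. Without the 57 cells Vim differed by 1.16 (adjusted p = 0.143 in the edgeR test) between the matrices in place of 1.90.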

How the results depend on the processing

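Counts of genes depended on the processing. Directions were followed only for the genes considered, most of which had passed in these same data. Many had been picked for the same sign in every mouse, so their kept directions do not measure how stable directions are. For the genes considered, 2786 values kept the direction and stayed on the same side of the threshold, 627 kept the direction and lost the call, 46 gained one and 26 reversed. With the mouse as a replicate block, which removes the differences between mice shared by both arms, the counts were 3207, 576 and 828 between the matrices on days 0, 3 and 5, 4975 and 1390 for the steps to day 3 and day 5 in collagen, 1676 from day 3 to day 5 in Matrigel, and 704 and 1809 for the change of the matrix difference by day 3 and day 5. Of the passing genes considered, the block ended only the call of Lce3c on day 0 (adjusted p = 0.0545). It ended the set test calls of immediate early and mitochondrially encoded genes from day 0 to day 3 in collagen (adjusted p = 0.103 each) and of mitochondrially encoded genes from day 3 to day 5 (adjusted p = 0.144), and beyond these and the values in the report it ended no other call of a gene or list described there. The DESeq2 Wald test gave 1467, 182 and 261 between the matrices, 472 and 559 from day 3 to day 5 in collagen and Matrigel, and 161 and 552 for the changes; DESeq2's size factors gave 15 for the change by day 3. With limma on log values averaged over cells there were 276, 14 and 295 genes between the matrices, 703 from day 3 to day 5 in Matrigel and 2 for the change by day 3. Without a filter on low counts the steps from day 3 to day 5 gave 95 and 217 genes and the changes 0 and 89. Fitting only the groups compared, with fewer sums to estimate the spread, gave 297 and 0 genes between the matrices on days 0 and 3, 75 and 2 from day 3 to day 5, and 0 for the change by day 3. All cells gave 0 genes for the change by day 3, and at least 100 cells per sum gave 9 for it and 7 between the matrices on day 3; day 5 Matrigel comparisons could not be made at that minimum. Subtracting the change in 4T1, a lone sum per pool assumed to vary like the other groups, gave 403 genes from day 0 to day 3 in collagen, 1330 in Matrigel and 82 from day 3 to day 5 in Matrigel, of which 233, 1075 and 7 were also called without it. Except where stated, the cause was not tested.

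Of the alternatives chosen after seeing the data, leaving out the 57 mouse-labelled cells of the 4T1 cluster gave 23 genes for the change by day 3, and with the replicate block as well 3200, 645 and 881 between the matrices, 5251 and 1443 in collagen, 1731 from day 3 to day 5 in Matrigel, and 669 and 1819 for the changes. At least 10 cells per sum, which admits mouse 1 in Matrigel on day 5, gave 191 genes between the matrices on day 5, 551 from day 3 to day 5 in Matrigel, and 18 and 353 for the changes. Without the cluster of few UMIs every count stayed within 1.5 times the reported one.

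Leaving out each mouse in turn gave 81 to 799, 1 to 58 and 0 to 276 genes between the matrices on days 0, 3 and 5, 992 to 3016 and 23 to 349 for the steps in collagen, 3288 to 4965 and 14 to 610 in Matrigel, and 0 to 1 and 0 to 254 for the changes; where 1 Matrigel sum remained on day 5, it was assumed to vary like the other groups. Rsad2 from day 3 to day 5 in Matrigel ranged from -0.90 to 6.21.

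The share of Vim positive cells kept its direction in all settings, with leave-one-out ranges of 4.91 to 6.60, 12.1 to 22.9 and 23.8 to 40.9 points; the exact permutation p fell to 0.0286 with 2 or more UMIs on day 0 (5.71 points) and day 3 (15.1) and with all cells on day 0 (7.50). The Krt14 share passed on day 0 without thinning (-9.72), and its difference reversed on day 3 without thinning (4.29), at 1000 UMIs (6.23), with all cells (1.39) and by mouse left out (-3.89 to 3.54), and on day 5 without thinning (-1.13). Depth limits these shares, since at 2000 UMIs per cell a low transcript is missed in most cells.

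After subtraction of 4T1, Ctgf (0.80), Cyr61 (0.36), Dusp6 (0.53), Jam2 (-3.46), Nme2 (-0.06), Cdk2ap1 (0.26) and S100a4 (1.16) reversed from day 0 to day 3 in collagen, Dusp6 (0.06), Plau (0.80), Krt5 (-0.48), Epcam (0.16) and Cdk2ap1 (0.25) in Matrigel, Tuba1a (-1.65) from day 3 to day 5 in collagen and Hes1 (-1.98) in Matrigel. S100a4 was also reversed in collagen without the 57 cells with the block (0.03). Vim, which did not pass from day 0 to day 3 in either matrix, reversed in collagen without the 57 cells (2.11, and 2.02 with the block), with limma on log averages (0.69), after subtraction of 4T1 (0.27) and by mouse left out (-0.95 to 0.41). In Matrigel it reversed in the same settings (1.36, 1.49, 0.12, 0.30, and -0.57 to 0.01). Settings fixed in advance on a size rule, a minimum CPM and the scaling of ratios were not run, since they were for a design without known mice.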

Other observations

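In this part the tests on chromosome 6, the 4T1 tests on genes that jumped between pools, and all counts of other splits were chosen only after the results were seen, except the test of the wide chromosome 6 region and that of shared 3' ends. Some fixed gene lists went both ways between day 0 and day 3. Of 18 S phase genes, 2 rose and 7 fell in Matrigel (2 and 10 adjusted over the list alone) and 1 rose and 3 fell in collagen (1 and 5), with adjusted p = 0.908 and adjusted p = 0.945 with an estimated correlation, while the mitotic list rose in Matrigel in 10 of 19 genes. Of 16 unfolded protein response genes, 4 rose and 6 fell in Matrigel (5 and 7 adjusted over the list alone) and 1 rose and 4 fell in collagen (1 and 5). Of 18 epithelial junction genes, 7 rose and 2 fell in Matrigel (7 and 2 adjusted over the list alone), the 2 being Cdh1 (-0.92) and Epcam (-0.55), and the set test gave an adjusted p of 0.589. Of 13 mitochondrially encoded genes 8 rose and 1 fell in Matrigel (11 and 1 adjusted over the list alone) and 4 rose and 1 fell in collagen (5 and 1), with adjusted p = 0.84 and adjusted p = 0.945 with an estimated correlation.

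A set of 90 genes, 36 higher and 54 lower, changed by at least 3 on the log2 scale between the day 0 and day 3 pools in both matrices. Their 3' ends were shared with another gene in 26 of 89 cases (29.2%) against 633 of 13085 other genes (4.84%), a ratio of 6.04 (Fisher's exact test, p = 9.73e-14), so counting of shared reads may be part of the pattern. Over all 90 genes, 12.2% changed in 4T1 in the same direction by at least 50% as much, no more than the 12.2% of 663 comparison genes, but 73 of them were under 10 CPM in 4T1; among the 17 at 10 CPM or more, a restriction made after the first value was seen, it was 64.7% (11 genes), against 26.4% of 295 comparison genes. Of these 17 genes 12 had a shared 3' end, as had 9 of the 11, so both candidate explanations rest on nearly the same genes. A difference between the pools that 4T1 shares is thus a candidate explanation for genes such as Nme2 and Cdk2ap1. Day and pool coincide, so the part of the set too low in 4T1 stays open, and a biological change of those genes was not tested.

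In mice 1, 2 and 3 the 40-gene window highest over 4T1 lay on distal chromosome 6 (medians 1.72, 1.86 and 1.32; next chromosome 0.64, 0.69 and 0.74), and in mouse 4 on chromosome 5 (0.77). For a gain of the whole region from 119.9 to 149.6 Mb in all 3 mice, a median of at least 1 in every sum had been set. Lowest medians of 0.36 in mouse 2 and 0.43 in mouse 1 over its 107 genes argue against a gain of that size. The sums of mice 1 and 2 lay between 0.36 and 0.66 and those of mouse 4 between 0.19 and 0.25, so a smaller gain stays open. In mouse 3 the sums lay between 0.67 and 1.01, and its own segment ran from 120.8 to 147.3 Mb, so a wide gain in that mouse stays open. Over the shared segment from 138.1 to 147.3 Mb, defined afterwards, the 11 sums of days 0 and 5 lay between 0.67 (38 cells) and 2.63 with the next lowest at 1.23, so a copy number gain in the tumours may explain it but was not decided by the bounds set for it. Macrophage-like and fibroblast-like cells of these mice (282 cells) had a median of -0.12, which argues against an inherited variant, and tumour cells of mouse 4 had 0.07, which argues against a loss in 4T1. The DNA was not analysed here, and 26 such cells of mouse 4 had a median of 0.73.

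Other splits of the same sums were counted for 5 further comparisons, 35 splits each with the real one included. These splits ignore the pairing by mouse. Over all 35, only the real split gave as many genes for the matrices on day 0 (927 genes, highest other 5). The same held for day 3 against day 0 in collagen (2581, highest other 9) and in Matrigel (5157, highest other 19). It also held for day 5 against day 3 in collagen (152, highest other 0). Sums of a mouse resemble each other, so splits that join them are not equivalent to the real one and cannot exclude chance. For the matrices on day 3, 2 splits gave as many genes. These were the real one with 27 genes and another with 33 that joined collagen mice 1, 2 and 3 with Matrigel mouse 2. Of the 8 splits that part as many pairs of a mouse as the real one, the highest other gave 0 genes in each of these comparisons, but 8 are too few for a share under 0.05.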
